A study of Equus caballus with 6 samples.

How the data were processed

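Total RNA of leukocytes from the buffy coat was labelled with Cy3 and hybridised to a 1-colour Agilent horse array, 1 array for each of 6 samples, per the labels. Blood (6 ml) was taken into EDTA tubes and centrifuged at 3000 rpm for 10 min at 4 °C, per the labels' protocols. Each deposited file holds the spots of 1 array as read by Agilent Feature Extraction 10.10.1.1 with the protocol GE1_1100_Jul11, per the file headers. Its values are a processed signal, an intensity that Feature Extraction background-subtracted and did not normalize between arrays, per the file headers. The header names the EquCab1 build, and no coordinate is used here.

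Samples were grouped by the labels into 3 before and 3 after exercise, and the number of the horse in the labels (1, 2 or 4) pairs a sample before with a sample after exercise of the same animal. Same-numbered arrays also deviated together from their group means, with correlations across probes of 0.36, 0.40 and 0.23. The comparison named in the labels was run without the horse as a block, and the fit with that block is an alternative.

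The log2 of the processed signal was taken and the array's 75th percentile over 43803 non-control spots was subtracted. Spots flagged as non-uniform or population outliers (67 to 169 per array) were left out, 1417 control spots were left out, and spots of 1 probe were averaged. A probe was kept where it was well above background on at least 3 of the 6 arrays, which left 29571 of 43603 probes. Of these, 29570 could be tested. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. Errors given as SE are moderated standard errors of limma from 3 against 3 arrays. Horses were compared with limma's moderated F-test, with exercise in the model. The horse samples are separate animals, so the spread between arrays of a group includes that between animals. An SE from this fit therefore does not measure the spread of the changes within horses. Of the probes kept, 28.6% changed the same way in all 3 horses, where 25% are expected for independent directions. The changes of horses 1 and 2 were not independent (r = 0.60 across probes). The 25% therefore does not apply here, and no agreement of the 3 horses is read from the share.

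Probes were named through the RefSeq accession in the files, without versions, and a table of RefSeq genes of the assembly TB-T2T. This matched 1979 probes to 870 genes, 829 of them with a gene symbol, and 41624 probes stayed without a name here, 31722 of which carry an Ensembl transcript identifier. A gene stands for its brightest kept probe over all arrays, and 562 named genes could be tested. Of 232 genes with several kept probes, 72 had a probe whose change has the other sign. No probe named here was below the background mark on every array of a group.

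The genes named were fixed before the data were examined by a rule with 4 parts. They are the 10 highest and 10 lowest genes past the threshold and changed alike in all 3 horses, filled where fewer pass, in order of p, with genes changed by at least 1 (log2) alike in all 3 horses. They are further the 3 members with the smallest p in each of 22 gene lists, 20 genes set in advance where measured, and the 10 genes with the smallest p between horses. Of the genes this rule takes, 2 are not reported here. The 22 lists cover blood cell types (neutrophil, T cell, NK and cytotoxic cell, B cell, monocyte, platelet, erythroid, eosinophil and basophil), antigen presentation, heat shock, glucocorticoid, immediate early, inflammatory and interferon responses, antioxidant genes, glycolysis and hypoxia, oxidative phosphorylation, fatty acid use, apoptosis, adhesion and trafficking, cell cycle and ribosomal proteins. Lists with at least 5 measured members (10 lists) were tested with camera of limma at a preset correlation of 0.01, and with an estimated correlation and fry beside it.

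Alternatives were normexp background correction (offset 50), quantile and median normalization, no filter or a stricter filter on dim probes, flagged spots kept, the horse and the slide as blocks, slide 1 alone, array weights, trended and robust variance, the mean of a gene's probes, and each horse or array left out. Normexp used the median spot signal in place of the mean. The first array column of the horse 4 array before exercise was left out as an alternative chosen after seeing the data. The fits were tested on simulated data with the spread within the groups of these arrays and 200 changed probes among 29351. Apart from the changes added, the simulated probes varied independently of each other and of horse and slide. For the comparison of the groups, 4% of probes changed by 1 on the log2 scale were recovered, 60% of those changed by 2, 92% of those changed by 4 and 100% of those changed by 6. With the horse as a block the shares were 0%, 6%, 88% and 98%. With slide as a block they were 0%, 6%, 74% and 90%, and in slide 1 alone 0%, 0%, 50% and 80%. With horse and slide as blocks no changed probe was recovered at any of these sizes. The real arrays of a horse deviated together, so these shares do not show what a block gains or loses on the real arrays. A list of 9 genes shifted by 0.5 was called among 556 simulated genes. In the real data the estimated correlation within lists ran from -0.002 (interferon response) to 0.82 (ribosomal proteins). The simulated result therefore does not carry over to lists whose members are correlated.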

Results

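Gene expression was measured in leukocytes of the buffy coat, the white-cell layer of centrifuged blood, from 3 neutered male warmblood horses. Each horse, numbered 1, 2 and 4 in the labels, gave 1 sample before and 1 after exercise, so that 3 arrays stood in each group. The labels of the samples taken after exercise carry the words 60 min, while the protocol describes sampling right before and right after the exercise, so the time since exercise is not settled here. The question was which transcripts of circulating leukocytes differ after exercise. Between 64.1% and 69.4% of the spots on each array were well above background, no spot was saturated, and the number of arrays limits the precision. The arrays lay on 2 slides: slide 2 held the samples of horses 1 and 2 taken before exercise, and slide 1 held the other 4 arrays. Pearson correlations between arrays, across probes, ranged from 0.940 to 0.987.

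After exercise no named gene passed the test, and the genes with the largest shifts in a shared direction were few. The lowest values relative to before exercise belonged to CYP19A1, the aromatase that makes oestrogens, with a log2 change of -3.21 (SE 1.12), and to SULT1E1, an oestrogen sulfotransferase, with -1.15 (SE 0.59). SERPINA14, the uterine serpin, had -1.005 (SE 0.40). On the higher side stood IL23A, which encodes a cytokine subunit, with 2.14 (SE 1.51), the haemoglobin genes HBB with 1.37 (SE 1.77) and HBA2 with 1.05 (SE 1.68), and the cytokine IL6 with 1.07 (SE 0.54). All 7 shifted the same way in all 3 horses by at least 1 on the log2 scale in the mean, but each had an adjusted p of 0.999 in limma. With normexp background correction of the median spot signal the change was -1.82 for CYP19A1, 0.9985 for IL23A, 0.97 for HBA2, 0.34 for IL6 and -0.16 for SERPINA14, while SULT1E1 (-1.11) and HBB (1.33) stayed close to the values above.

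The 3 horses contributed unequally to these shifts. CYP19A1 differed by -4.12 in horse 1 and -4.92 in horse 2, against -0.60 in horse 4, and SULT1E1 by -1.48, -1.91 and -0.04 in the same order. HBB was higher by 0.90, 2.80 and 0.42, and HBA2 by 0.93, 2.16 and 0.06. IL6 was higher by 2.03, 0.28 and 0.90, but its probe was well above background on only 1 of 3 arrays before and 2 of 3 after exercise. SERPINA14 was measured above background on 2 of 3 arrays before and 1 of 3 after, and CYP19A1 on 3 and 2. The IL23A value rested on horse 4, with 5.86 against 0.46 and 0.11 in the others. Its probe lies in the first column of the array, where the horse 4 sample taken before exercise had a run of dark spots, and without that column on that array its change was 0.19.

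**Figure D1:**
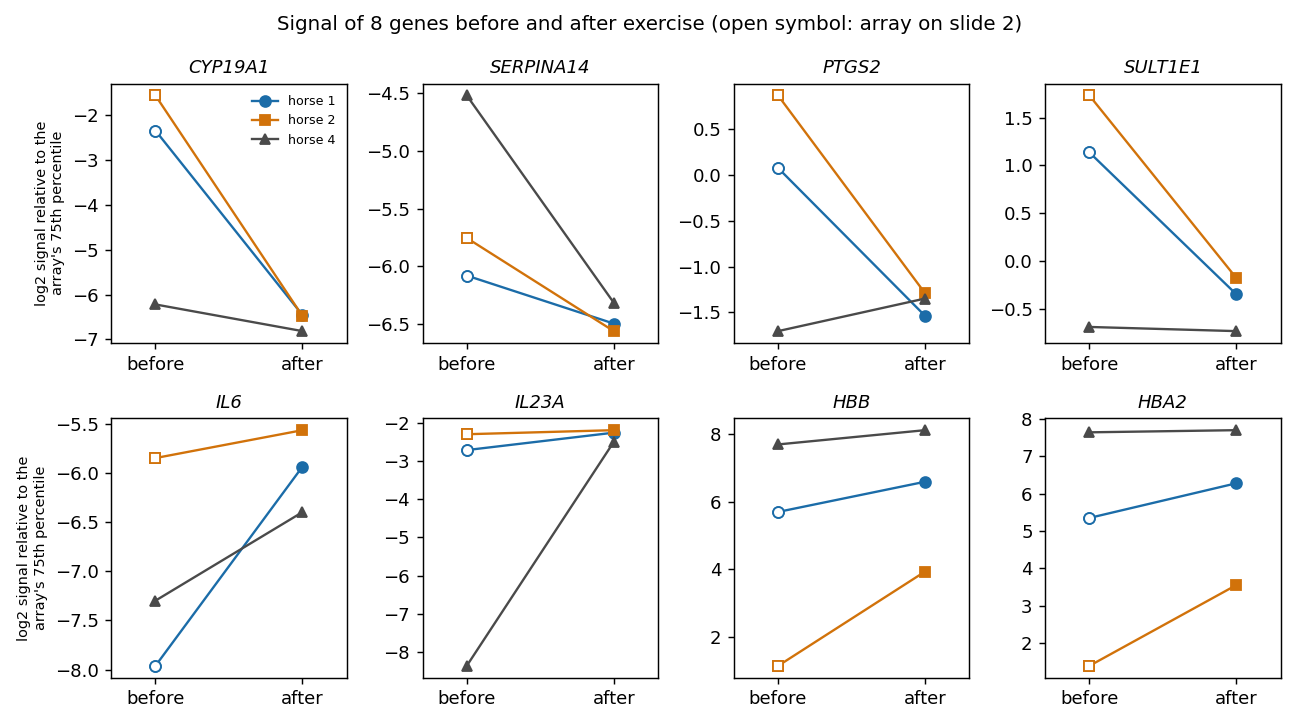
Signal of 8 genes before and after exercise, as log2 signal relative to the array's 75th percentile on the vertical axis, with 1 line per horse and open symbols for the arrays on slide 2. CYP19A1, SULT1E1 and PTGS2 were lower after exercise in horses 1 and 2 (PTGS2 by -1.61 and -2.16), and the before-exercise value of horse 4 lay near the after-exercise values of all horses.

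Across all probes, limma called 0 of 29570 probes at an adjusted p under 0.05, and 855 probes (117 higher and 738 lower) had an unadjusted p under 0.05, where 1478.5 are expected by chance. That fit does not use the pairing by horse: with the horse as a block 1797 probes had an unadjusted p under 0.05, and without the horse 4 array taken before exercise 5190, so whether the count lies below or above chance depends on the fit. Of 562 named genes tested, 0 were called and 16 had an unadjusted p under 0.05, 4 higher and 12 lower. The median change of all probes was 0.04 and the median SE of a change was 0.26. The count depended on 1 array: without the horse 4 array taken before exercise, limma called 595 probes (13 higher and 582 lower) and 12 named genes, among them CYP19A1 (log2 change -4.64, adjusted p = 0.0069), PTGS2 (-1.86, adjusted p = 0.039) and SULT1E1 (-1.85, adjusted p = 0.038); without both arrays of horse 4 it called 20, all lower. Leaving that array out puts every before-exercise array on slide 2 and every after-exercise array on slide 1, so that exercise and slide cannot be told apart. With array weights, which ranged from 0.219 for that array to 15.3 for the horse 1 array after exercise, 1638 probes (137 higher and 1501 lower) and 33 named genes were called.

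Within slide 1, the 3 arrays after exercise could be set only against the horse 4 array before exercise. There CYP19A1 had a log2 change of -0.36, SULT1E1 of 0.27, SERPINA14 of -1.94, IL6 of 1.34 and HBB of -1.48, and none of these 5 passed the test, which in simulated data recovered 0% of changes of 2 on the log2 scale. Counting each gene by its brightest probe, IL23A and PIAS3, an inhibitor of STAT3 signalling, were the 2 named genes called. Dimmer probes of PTGER2, MDH2, COX17, ACVR2A and RPS26 were called too, and all 7 called probes lie in the first array column. These genes other than IL23A and RPS26 were named after their values were seen. In all, 122 probes were called in slide 1 alone (120 higher and 2 lower), 131 with slide as a block (127 higher and 4 lower) and 116 with horse and slide as blocks (113 higher and 3 lower). Of these, 119, 126 and 111 lay in the first array column, which holds 1.02% of the probes tested. On the horse 4 array before exercise, 215 of 226 odd-row spots of that column (95.1%) were not well above background, against 35.4% to 39.8% on the other arrays. With that column of that array left out, which was decided after seeing the data, 0 probes were called in each of the 3 fits. For the column itself this was bound to follow, since only 2 of its probes could still be tested. The 3, 5 and 5 called probes outside it, none of them named, kept their changes (2.80 to 2.87, 2.21 to 4.48 and 3.48 to 5.78 in size, with SE from 0.20 to 0.50), their SE and their unadjusted p. Their calls ended only through the adjustment over all probes, with smallest adjusted p of 0.98, 0.95 and 0.48.

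**Figure D2:**
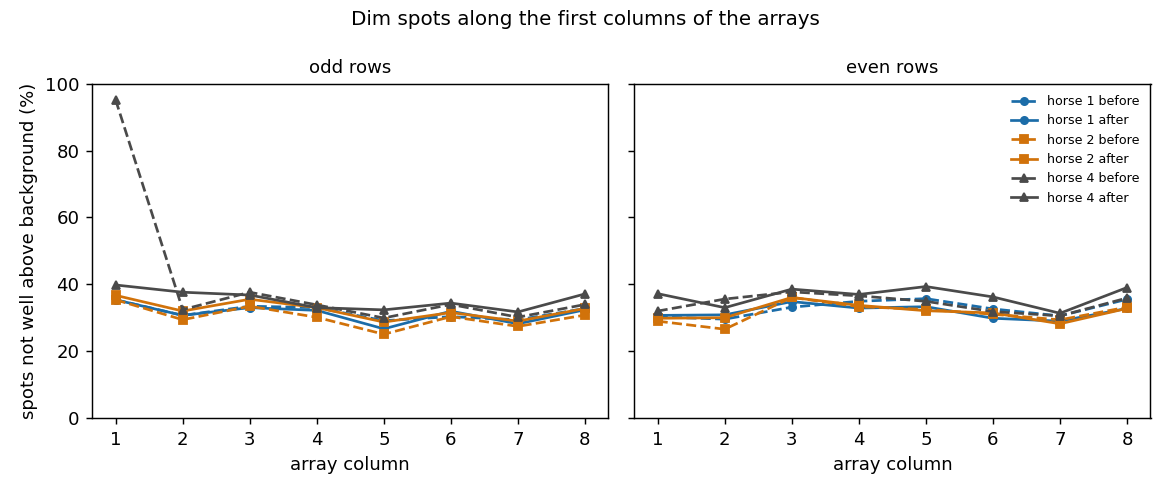
Percent of spots not well above background in array columns 1 to 8, for odd rows on the left and even rows on the right, with 1 line per array (broken lines before exercise). In column 1 and odd rows, the horse 4 array before exercise stood at 95.1%, and in even rows at 32.0%.

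CYP19A1 and PTGS2 belonged to a larger set of probes that were lower after exercise in horses 1 and 2. Across 29351 probes measured on all 6 arrays, the changes in horses 1 and 2 correlated with r = 0.60, while r was -0.10 between horses 1 and 4 and -0.12 between horses 2 and 4. Probes are not independent replicates, so these values only describe the 3 horses, whose changes share no array. In horses 1 and 2 the array before exercise lay on slide 2 and the array after on slide 1. Both changes therefore hold the same difference between slides, while the change of horse 4 lies within slide 1. In 461 probes the signal was lower by more than 1.5 on the log2 scale in both horses 1 and 2, and in 11 it was higher by as much. The 461 probes include 6 named genes, chosen after their values were seen: CYP19A1, PTGS2 (which makes prostaglandins in inflammation), the chemokine CCL13, the serotonin receptor HTR4, the hormone gene GAST and the integrin ITGAX. The median change of all 461 probes was -2.14 in horse 1 and -2.60 in horse 2, and 0.0051 in horse 4 (quartiles -0.22 and 0.28). Probes of ITGAX disagreed: 2 of its 7 probes had changes of -1.94 and -1.39 over all horses, and the other 5 lay between 0.01 and 0.13.

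**Figure D3:**
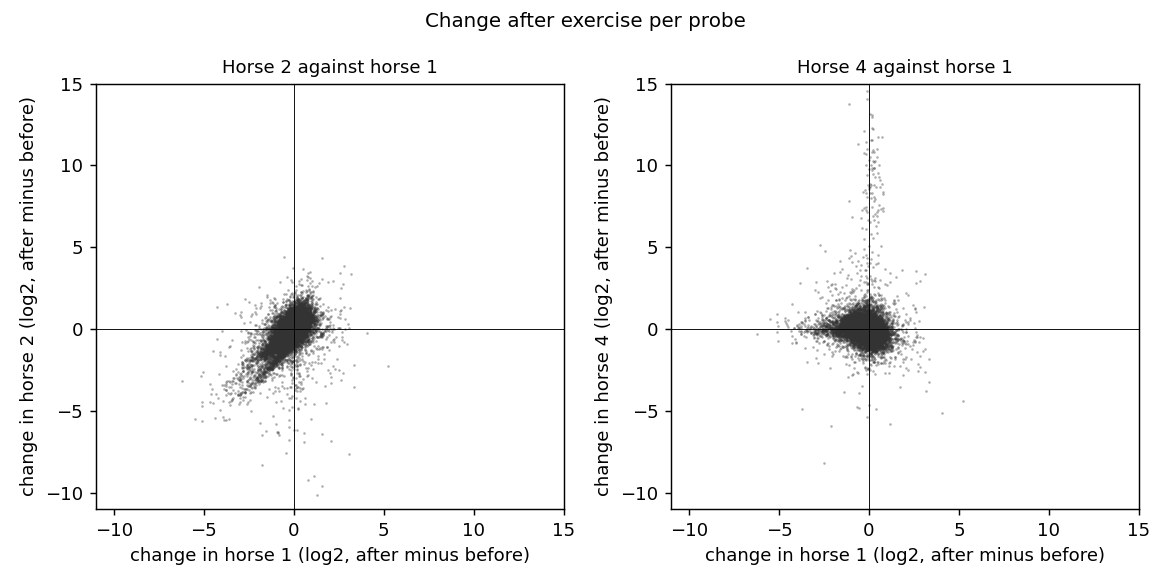
Change after exercise per probe (log2, after minus before), with horse 1 on the horizontal axis and horse 2 (left) or horse 4 (right) on the vertical axis, and 1 point per probe. Horses 1 and 2 share a tail of lower probes (r = 0.60 over all probes), and the column of points with a high change in horse 4 alone holds spots of the dark edge.

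Among gene lists, cytosolic ribosomal protein genes came closest to a shift, without passing. The 11 measured members had a median log2 change of 0.20 (limma camera, adjusted p = 0.093; adjusted p = 0.93 with an estimated correlation), with medians of -0.08, 0.06 and 0.56 in horses 1, 2 and 4. RPL18 was higher in all 3 horses (mean change 0.49, SE 0.22), as were RPS4X (0.27, SE 0.22) and RPS26 (0.33, SE 0.28). With horse and slide as blocks, which leaves the pair of horse 4 alone, the list had a median of 0.56 and passed (adjusted p = 0.0079), but not with an estimated correlation (adjusted p = 0.82). The p-values of that fit do not measure any spread of the change in horse 4, which is a single difference. The shift of the list depended most on the after-exercise array of horse 4: without it the median was 0.003 (adjusted p = 0.75), and without both arrays of that horse -0.007 (adjusted p = 0.71). Without the before-exercise array of horse 4 it was 0.22 (adjusted p = 0.29), of horse 2 0.14 (adjusted p = 0.38) and of horse 1 0.25 (adjusted p = 0.058). Without horse 1 or horse 2 the list passed at the preset correlation, at medians of 0.33 (adjusted p = 0.018) and 0.27 (adjusted p = 0.017), and also without the after-exercise array of horse 1 (0.29, adjusted p = 0.031) or horse 2 (0.35, adjusted p = 0.0089). After quantile normalization the median was 0.01 (adjusted p = 0.90), and with array weights -0.03 (adjusted p = 0.73). Of the 7 antioxidant and redox genes measured, from 33 listed, 5 were higher in all 3 horses. The list median was 0.23 (limma camera, adjusted p = 0.21, and adjusted p = 0.93 with an estimated correlation). Examples are SOD1 (0.31, SE 0.20) and GPX1 (0.47, SE 0.35), which detoxify superoxide and peroxides, and the ferritin light chain FTL (0.24, SE 0.23).

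Inflammatory and stress lists did not pass, as far as their genes could be named and measured. Measured were 15 of 36 inflammatory, 9 of 42 interferon response and 6 of 30 heat shock genes listed. The 15 inflammatory cytokine and NF-kB target genes had a median of 0.08 (adjusted p = 0.84). TNF had a change of 0.21 (SE 0.53), with -0.64, -0.27 and 1.54 in horses 1, 2 and 4. CXCL8, the neutrophil-attracting chemokine, had 0.18 (SE 0.71), with 0.13, 0.07 and 0.35 in horses 1, 2 and 4. TLR4, the receptor for endotoxin, had 0.27 (SE 0.31). IL10 had 0.08 (SE 0.19) and PTGS2 -1.14 (SE 0.61). IL1RN, the interleukin 1 receptor antagonist, had -0.0006 (SE 0.20), and 9 of its 10 probes had the other sign. The 9 interferon response genes had a median of 0.07 and a mean of -0.02 (adjusted p = 0.91). In this list SAMD9, an antiviral factor, was lower in all 3 horses (-0.73, SE 0.24), with the smallest p adjusted over the list alone of any list, 0.18. OAS2 had 0.25 (SE 0.19) and OASL 0.16 (SE 0.17). The 6 heat shock and chaperone genes had a median of 0.13 (adjusted p = 0.91), with HSPA1B at 0.27 (SE 0.44), HSP90AB1 at 0.21 (SE 0.35) and HSP90B1 at -0.19 (SE 0.24).

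Metabolic and trafficking lists did not pass either. Here too most listed genes were not measured: 11 of 37 glycolysis and hypoxia genes were, 9 of 30 of adhesion and trafficking and 5 of 34 of apoptosis. For oxidative phosphorylation it was 3 of 57, and for fatty acid use 2 of 36. The 11 glycolysis and hypoxia genes had a median of 0.19 (adjusted p = 0.91), with the glucose transporter SLC2A1 at -0.64 (SE 0.32), VEGFA at -0.35 (SE 0.24) and GAPDH at 0.29 (SE 0.24). The first 2 of these were not stable to processing: with normexp, which was run on the median spot signal in place of the processed signal, SLC2A1 had -0.02 and VEGFA 0.06. Their probes were well above background on 2 and 1 of the 3 arrays after exercise. SLC2A1 and VEGFA have other probes of the opposite sign, as do OASL, CD40, FASLG, IL4 and SPARC. The 9 adhesion and trafficking genes had a median of 0.09 (adjusted p = 0.37), and S1PR1, which guides lymphocytes out of lymphoid tissue, was higher in all 3 horses (0.61, SE 0.32), beside CD44 (0.24, SE 0.21) and SELPLG (0.38, SE 0.36). The 5 apoptosis genes had a median of 0.08 (adjusted p = 0.91), with FASLG at 0.09 (SE 0.26) and PMAIP1 at -0.07 (SE 0.20). SDHB (0.29, SE 0.22), ATP5F1B (0.10, SE 0.28) and COX7C (0.09, SE 0.26) were the 3 oxidative phosphorylation genes measured, and CPT1A (0.18, SE 0.36) and PPARA (-0.10, SE 0.29) the 2 of fatty acid use; neither list was large enough to test.

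Markers of cell types in blood gave no call, but most listed markers were not measured. Measured were 7 of 26 NK and cytotoxic cell, 5 of 22 monocyte, 3 of 32 neutrophil, 3 of 25 T cell and 3 of 21 B cell genes. Of the glucocorticoid response it was 4 of 25, and of the immediate early response 2 of 31. The 7 NK and cytotoxic cell genes had a median of 0.09 (adjusted p = 0.91), with 0.35 and 0.46 in horses 1 and 2 and -0.36 in horse 4. GNLY, a cytolytic granule protein, was higher in all 3 horses (0.58, SE 0.49), CCL5 had 0.37 (SE 0.41) and NCR1 -0.31 (SE 0.21). The 5 monocyte genes had a median of 0.27 (adjusted p = 0.58), with TIMP1 at 0.49 (SE 0.48), CD68 at 0.27 (SE 0.29) and CD14 at 0.29 (SE 0.44). TIMP1 was higher in all 3 horses, by 0.49, 0.53 and 0.45 in horses 1, 2 and 4. It did not pass in limma with the horse as a block either (adjusted p = 0.75). Lists with fewer than 5 measured members were not tested. Their members were FCAR (0.17, SE 0.20), MMP9 (0.23, SE 0.30) and LTF (0.49, SE 0.83) for neutrophils, CD28 (0.27, SE 0.43), CD2 (0.08, SE 0.29) and IL7R (-0.01, SE 0.48) for T cells, and TNFRSF13C (-0.31, SE 0.18), PAX5 (-0.11, SE 0.31) and FCER2 (0.09, SE 0.34) for B cells. SELP (-0.11, SE 0.21), ITGA2B (0.28, SE 0.61) and SPARC (0.22, SE 1.31) stood for platelets, and IL4 (0.17, SE 0.34) and FCER1A (0.10, SE 0.43) for basophils and eosinophils. The erythroid list held only HBB and HBA2. CD74 (0.30, SE 0.34), B2M (0.22, SE 0.26) and CD40 (-0.10, SE 0.28) were the leading genes of 4 in antigen presentation. DDIT4 (0.37, SE 0.51), ANXA1 (0.15, SE 0.22) and NR3C1, the glucocorticoid receptor (-0.12, SE 0.20), led the 4 of the glucocorticoid response. RGS1 (0.23, SE 0.29) and RGS2 (0.08, SE 0.28) were the 2 immediate early genes, and no probe could be named as one of the 37 cell cycle genes listed. In each list 0 members passed over all probes and 0 adjusted over the list alone. Directional and mixed fry tests called 0 of the 10 lists, and with slide as a block the 10 adjusted p-values ran from 0.13 to 0.93, and within slide 1 from 0.18 to 0.93.

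**Figure D4:**
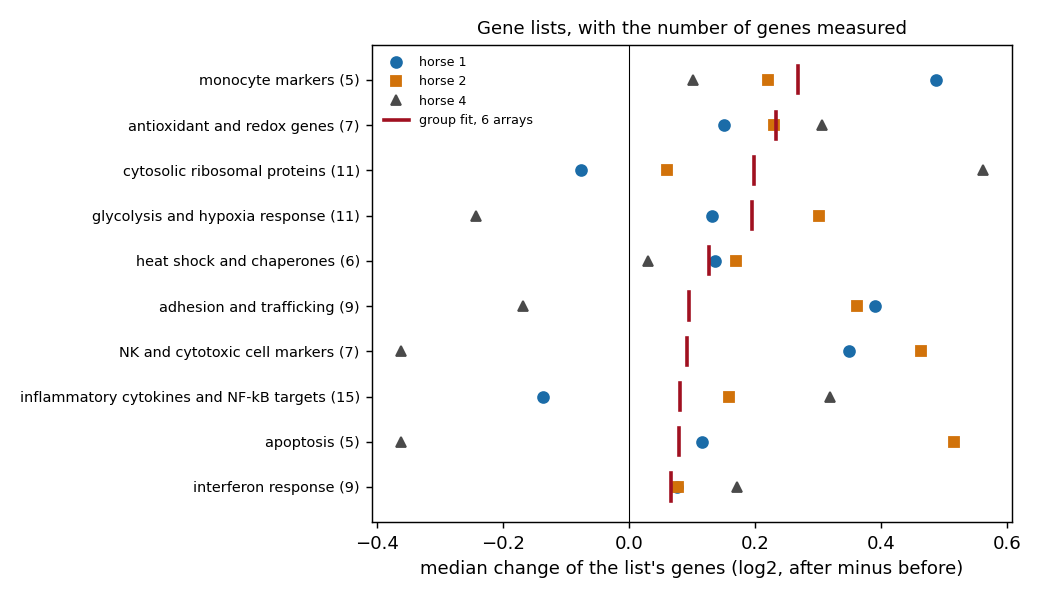
Median log2 change (after minus before) of the genes in each of the 10 lists tested, with 1 symbol per horse and a bar for the fit over 6 arrays; numbers in brackets count the genes measured. The median of the ribosomal list lay at 0.56 in horse 4 and at -0.08 in horse 1.

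Between the horses, few probes passed the test, while many more had a small unadjusted p. With exercise in the model, limma's F-test called 70 of 29567 probes, and 4580 had an unadjusted p under 0.05. In simulated data the test recovered 58% of probes shifted by 4 on the log2 scale in 1 horse. The simulated spread included that between animals, and the simulated arrays of a horse varied independently. That share therefore does not measure what the test recovers on the real arrays, and further differences may still have been missed. The named genes called were 5, of which 4 are given here. EQMHCC1, a class I histocompatibility gene, had mean log2 signals of 2.99, 2.53 and -1.97 in horses 1, 2 and 4 (adjusted p = 0.047). SPI2, a serine protease inhibitor, had -2.85, -6.28 and -2.36 (adjusted p = 0.047). CYP3A89, a cytochrome P450, had -2.31, -2.99 and -5.28, and CPNE8, a copine, -3.78, -1.61 and -4.61 (both adjusted p = 0.0496). SPI2 was measured above background on 2 of 3 arrays before and 3 of 3 after exercise, and another SPI2 probe had the opposite sign of change after exercise.

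The next 5 genes by p did not pass. The acute-phase gene SAA was lowest in horse 2, at -5.78, against -3.29 in horse 1 and -2.76 in horse 4 (adjusted p = 0.053). SAA1 (adjusted p = 0.054) and CYP3A93 (adjusted p = 0.051) were well above background on only 3 and 4 of the 6 arrays, so their levels near background are not compared. SPARC, a matrix protein stored in platelets, ranged from -3.06 in horse 2 to 1.04 in horse 1 (adjusted p = 0.057), and the interferon-induced IFI27 from 1.91 in horse 2 to 4.17 in horse 1 (adjusted p = 0.078). HBB ranged from a mean of 2.54 in horse 2 to 7.92 in horse 4 (adjusted p = 0.13). The count of 70 fell to 1 after quantile normalization, to 2 without the filter on dim probes and to 1 with slide as a block, and was 255 with exercise left out of the model.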

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

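Of the alternatives, the one with the first array column of the horse 4 before-exercise array left out was chosen after seeing the data. The count of 0 probes and 0 named genes called after exercise stayed at 0 with normexp, quantile and median scaling, both other filters, flagged spots kept, the replicate block (horse) and trended variance, and the replicate block changed no call. It moved to 131 probes and 2 named genes with slide as a block, 116 and 2 with the replicate block and slide together, 122 and 2 in slide 1 alone, where the lone before-exercise array is assumed to vary like the others, and 1638 and 33 with array weights, whose estimation stopped before convergence. Leaving out 1 horse or array gave 0 to 595 probes and 0 to 12 named genes. Without the dark column, the count was 0 in the group-only, replicate-block and slide fits, where all but 2 column-1 probes have no before-exercise array left on slide 1; elsewhere the cause was not tested. The number of lists called moved from 0 to 1, the ribosomal list, without the filter on dim probes, with the mean of a gene's probes and with the replicate block and slide (also without the dark column), and ranged from 0 to 1 with a horse or array left out. These calls use the preset correlation. With an estimated correlation, 0.82 in the main fit, the list did not pass in camera in the main fit (adjusted p = 0.93) or with the replicate block and slide (adjusted p = 0.82). Nor did it pass so with the replicate block (adjusted p = 0.97) or with slide as a block (adjusted p = 0.88). For the other settings that called the list, values with an estimated correlation are not given here. The count within slide 1 moved from 122 to 4 among probes well above background on all 6 arrays and to 0 without the dark column. The correlation of changes between horses 1 and 2 moved from 0.60 to 0.41 without the filter, and that of horses 1 and 4 from -0.10 to -0.20 with the strict filter. The count of probes differing between horses moved from 70 to 1 (quantile normalization), 2 (no filter), 1 (slide as a block) and 255 (exercise left out). Median scaling moved the median change of all probes from 0.04 to 0.13, while it was -0.017 without the filter on dim probes and -0.015 with slide as a block. Changes of named genes, none called, differed in sign from the value given in 352 of 2039 recomputed values, and those of lists in 52 of 280. Dim probes limit what can be said: 14032 of 43603 probes were not well above background on 3 arrays.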

Other observations

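Outside the genes fixed by rule, several named genes had an unadjusted p under 0.05 in limma and the same direction in all 3 horses. None passed the adjustment, and they were picked after their values were seen. In that fit 16 of 562 named genes had such a p, fewer than expected by chance, so they are no evidence of a response. SCOC, a Golgi and autophagy protein, had changes of -1.06, -0.86 and -0.51 in horses 1, 2 and 4 (mean change -0.81, SE 0.19). ROCK1, a kinase of actomyosin contraction, had -0.67, -0.64 and -0.30 (mean -0.54, SE 0.18), and LIG4, a DNA ligase of double-strand break repair, -0.93, -0.65 and -0.54 (mean -0.71, SE 0.27). PNMT, the enzyme that makes adrenaline from noradrenaline, was higher by 1.38, 0.27 and 0.83 (mean 0.83, SE 0.28), from a probe well above background on 1 of 3 arrays before and 3 of 3 after exercise.

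Of the tests below, only that of other probes of the same transcripts in the dark column and the counts over splits were set before their results were seen; the rest were chosen after. With slide as a block, 126 of 131 called probes lay in the first array column. On the horse 4 array before exercise 95.1% of the odd-row spots of that column were not well above background, against at most 39.8% on another array, although at most 1 of these spots was marked as an outlier. A rise of the transcripts in horse 4 is argued against: the called probes of that column were higher by a median of 7.89 in horse 4, while 238 probes of the same transcripts in other columns had a median change of 0.019 (quartiles -0.16 and 0.28). Dark spots along the array edge may therefore account for these calls, and what darkened them stays open.

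The 461 probes were chosen as lower by more than 1.5 after exercise in both horses 1 and 2. By that choice their signal was higher on each slide 2 array than on the slide 1 array of the same horse. Where the horse 4 arrays lay relative to slide 2 is not given here for the 461 probes as a set. In a fit of slide alone, with exercise left out, 1283 probes were called between slides (1193 higher on slide 2). With exercise in the model the slide term called 349. How many of the 461 probes were among those called in these fits is not given here. For the 461 probes, a fall shared by all 3 horses is argued against by horse 4. That horse did not enter their choice and had a median change of 0.0051 (quartiles -0.22 and 0.28). Brighter hybridisation or scanning of slide 2 is argued against by the spike-in probes, whose raw signal changed by a median of 0.01 in horse 1 and 0.50 in horse 2, in the other direction, though 1 of the 8 used had -2.14 in horse 2. Differences of single spots are argued against by 178 other probes of the same transcripts, with a median of -1.56 (quartiles -2.41 and -0.74) in horses 1 and 2, against 0.07 for all transcripts with several probes. Only the first of the 461 probes in each transcript was set aside, so the 178 can include further probes of the 461. A response of horses 1 and 2 that horse 4 lacked, and a difference in how the samples on slide 2 were handled or labelled, may each account for them and cannot be told apart, since slide and exercise coincide in these horses.

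Haemoglobin transcripts spanned a wide range. HBB lay at 5.70 and 6.60 in horse 1 before and after exercise, at 1.14 and 3.94 in horse 2 and at 7.70 and 8.13 in horse 4, a range of 6.99. Array scaling is argued against, since the arrays' 75th percentiles ranged over 16.8% of that on the log2 scale. HBB and HBA2 moved together, their difference ranging over 0.70, which is in line with a varying share of red-cell RNA in the buffy coat, but with 2 erythroid genes measured this cannot be told apart from a change in haemoglobin transcripts alone.

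The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 0 probes and the highest of the others 2. For lists the real split called 0 and the highest other 2. At an unadjusted p under 0.05 the real split had 855 probes, and the split that set both slide 2 arrays and the horse 2 array after exercise against the rest had 4805, though it called 0 after adjustment. When the before-exercise arrays were paired with the after-exercise arrays in the other 5 possible ways, the F-test between horses called at most 1 probe, against 70 with the pairs of the labels, and between 373 and 1626 probes had an unadjusted p under 0.05, against 4580. Among the 70 probes, horse 2 stood apart in 35, horse 4 in 20 and horse 1 in 15.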
